A study of Homo sapiens and Mus musculus with 44 samples.

How the data were processed

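Per the labels, the samples are bulk RNA sequencing libraries made with a TruSeq kit from flat, tube-forming, implanted and freshly sorted endothelial cells. RNA of the tube assay, plug and pre-plug libraries was extracted with a picopure kit and that of the other libraries with a qiagen kit, so no comparison mixes the kits. The deposited files hold counts of read pairs per gene name, not normalized, and the values are whole numbers with a different total per library. Per the submitters' processing notes, reads were aligned with STAR 2.6.0c. Per the file headers, featureCounts 1.6.2 counted fragments on exons grouped by gene name without a strand option. Per the file headers, human reads were placed on GRCh38.p12 with GENCODE 28 and mouse reads on GRCm38.p6 with GENCODE M17. Reads of antisense or overlapping genes are therefore not separated, and genes with near-identical copies share or lose reads.

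Files were joined by gene name. Human files held 56832 names, of which 148 lay on more than 1 chromosome, and 56318 were kept after genes of chromosome Y, XIST and TSIX were left out. Mouse files held 53656 names, all kept. Over 59 pairs of libraries of the same group, no pair was a copy of another, as chi-squared per degree of freedom (genes with at least 10 counts in the pair) ran from 15.7 to 702. A header named a plug alignment for 1 pre-plug library, which was kept as labelled. Totals ran from 708356 to 85266101 counts per library. Counting intervals (95% confidence, exact) and floors of 3 counts over a group cover counting error only. Bounds and ratios pool the counts of a group, and their values without each library of the higher group were added after the data were seen. Groups, comparisons, tests, gene lists, named-gene rules and most alternatives were set before the data were examined.

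Each comparison was fitted with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, after filterByExpr with a minimum count of 10 and TMM scaling, with Benjamini-Hochberg adjustment at 0.05. All tests were two-sided. The adult fit had tissue as a block. The tube assay was 1 fit over its 3 stages, and the interaction used the HUVEC and adult flat libraries in 1 fit, with 4 genes each way in place of 8 to be named if called. In total 8 comparisons and the interaction gave 9 tests. These p-values measure spread between the samples at hand, which may be technical. Named genes were ETV2, then up to 8 genes each way with the largest log2 fold change. They had to be called, to reach a mean of 5 CPM in the higher group and to have groups that did not overlap (for adult cells, the same sign in all tissues). From each list, up to 4 members with the smallest p were examples. Genes whose level can reflect a donor's genotype, and clone-based names, were never named, and a few single-gene results were withheld. MAP3K5, ADGRL3, GPC1, DIO2, the examples for the replicate block and the genes given per plug library were chosen after their values were seen.

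There were 25 gene lists, 18 for human and 24 for mouse libraries, tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and, as an alternative, with an estimated correlation. List adjustment ran over the lists of a comparison, and members were also adjusted over the list alone. Sets of the 200 genes highest in fresh and the 200 highest in cultured HUVEC were tested the same way in 4 comparisons that share no library with them, 8 tests in all. Overlaps of calls between comparisons and a list of 12 mouse germ cell markers were added after the count files were seen, and 1 of these markers, Kit, is also in the blood progenitor list. The cell cycle list was picked among the 18 for a paired test after list medians were seen, and the adjustment of that test over the 18 lists was set after earlier values were seen.

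The labels number replicates without saying what a number is, though they call the cultured HUVEC matched. Pairing was checked on residual log2 CPM after group means were removed, with a correlation above 0.1 in every pair as the limit. Same-number correlations were 0.491 to 0.727 in HUVEC R-VEC and CTRL-EC (others -0.559 to 0.268) and 0.543 to 0.835 by tissue in adult cells (others -0.549 to 0.456). They were 0.222 to 0.646, 0.244 to 0.424 and 0.182 to 0.291 between the stages of the tube assay.

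Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a filter at 1 CPM, the replicate block, no tissue block, only the 6 libraries of the compared tube stages, and leaving out each library or tissue. Leaving out numbered pairs under the block, and the HUVEC block in the interaction, were added after the data were seen. The fits were tested on simulated data with 200 changed genes. Counts were drawn with edgeR's spread per gene and the same mean level in all libraries apart from the change, without tissue or replicate differences. At 2-fold and 4-fold, edgeR recovered 18 and 71% in HUVEC, 42 and 92% in adult cells and 37 and 86% in the culture comparison. It recovered 1 to 8% and 48 to 52% in the tube assay, 0 and 31% in mouse, 5 and 52% in the interaction, and 0 and 0% in plugs. After that was seen, 16-fold and 64-fold were added, of which it recovered 62 and 73% in plugs and 81 and 92% in mouse. False calls made up 1.8 to 18.4% of edgeR calls at 2-fold and 4-fold, apart from plugs, where the only call was false. They made up 22.2 to 77.8% of DESeq2 calls. Gene types were taken from GENCODE 29 by name, then by current or older symbol, and by position where these gave none. Matching by name alone, tried first, covered only 51.1% of the genes higher in plugs, and all steps together covered 99.8%. No other organism's reads could be separated, since only counts were deposited.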

Results

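Read counts per gene were collected by RNA sequencing for 44 libraries in 13 groups, 40 libraries from human endothelial cells (EC) and 4 from mouse embryos. ETV2 is a transcription factor that specifies endothelial and blood fate in the embryo and is silent in mature vessels. R-VEC are endothelial cells in which ETV2 was switched on, and CTRL-EC are their matched controls. Primary human umbilical vein endothelial cells (HUVEC) were sequenced as CTRL-EC (n = 4) and R-VEC (n = 4) in flat culture. Adult endothelial cells from heart, aorta, lung, skin and fat gave CTRL-EC (n = 5) and R-VEC (n = 5). HUVEC were also sequenced freshly sorted (n = 4) and after culture (n = 4). R-VEC from a tube-forming assay came from the flat start (n = 3), 1 week (n = 3) and 4 weeks (n = 3). R-VEC were also taken before injection into mice (n = 2) and sorted for GFP from implanted plugs after 1 month (n = 3). Mouse CD31+ cells of E9.5 embryos were sorted by an Etv2-Venus reporter into positive (n = 2) and negative (n = 2) fractions. Total counts per library ran from 22250307 to 85266101 outside the plugs, and plugs 1, 2 and 3 had 12175445, 708356 and 2772079.

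ETV2 itself (GRCh38 chromosome 19, 35641745 to 35644871) was higher in R-VEC than in CTRL-EC of the flat cultures. It averaged 0.73 ± 0.17 CPM (counts scaled to the library total, ± SD, n = 4) in HUVEC CTRL-EC and 332 ± 119 CPM (n = 4) in HUVEC R-VEC. Adult cells had 0.82 ± 0.17 CPM (n = 5) without and 425 ± 221 CPM (n = 5) with ETV2. Fresh and cultured HUVEC had 0.62 ± 0.25 and 0.80 ± 0.09 CPM (n = 4 each). The tube assay gave 191 ± 63.7 CPM at the flat start, 433 ± 318 CPM at 1 week and 114 ± 42.8 CPM at 4 weeks (n = 3 each). The level was 274 ± 15.6 CPM (n = 2) before injection and 55.3 ± 67.2 CPM (n = 3) in plugs, where plug 2 held only 2 ETV2 counts (2.82 CPM). Mouse Etv2 (GRCm38 chromosome 7, 30633616 to 30635852) stood at 152 ± 64.4 CPM in Venus-positive and 0.80 ± 0.45 CPM in Venus-negative cells (n = 2 each). Counts of an introduced ETV2 sequence and of the gene itself were not separable.

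**Figure D1:**
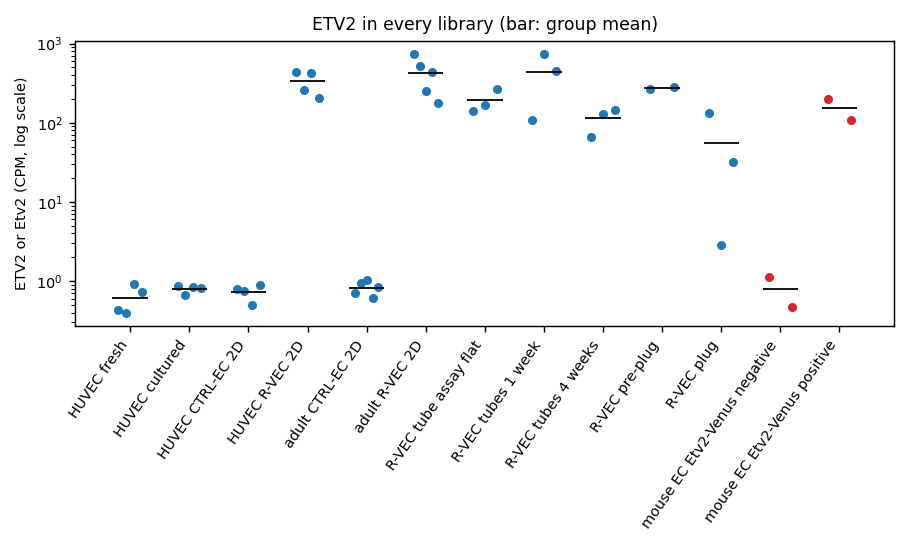
ETV2 or Etv2 level in CPM for each library (points, log axis) by group, with the group mean. HUVEC R-VEC libraries lie between 205 and 443 CPM, while HUVEC CTRL-EC libraries lie between 0.50 and 0.89 CPM.

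The comparison of HUVEC R-VEC with CTRL-EC asked what ETV2 changes in a mature endothelial cell kept in the same medium. The collagen IV chains COL4A1 and COL4A2 and the RAS and RAP1 activators RASGRP2 and RASGRP3 rose in R-VEC. The hemidesmosome integrin chain ITGB4, the flow-induced factor KLF2 and the collagen receptor chain ITGA10 fell. Of 26 pan-endothelial genes none was called without a block, while the replicate block called 7 higher and 5 lower. edgeR called 338 of 15230 genes, 223 higher and 115 lower in R-VEC. Single libraries mattered for this count: it was 89, 75, 92 and 837 without CTRL-EC 1, 2, 3 and 4, and 100, 78 and 223 without R-VEC 1, 2 and 3. With the shared replicate number as a block, 3340 genes were called (1652 higher, 1688 lower), among them all 338. The blocked count was 1780, 609 and 1024 without the pairs numbered 1, 2 and 3.

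Among the genes that rose most in HUVEC R-VEC, TBX15, a mesodermal T-box factor (chromosome 1, 118883046 to 118989556), rose by 9.65 ± 0.52 (log2 fold change ± SE; edgeR adjusted p = 0.000228), from a mean of 0.0573 to 48.2 CPM. ETV2 rose by 8.87 ± 0.37 (edgeR adjusted p = 5.37e-05). ALOX5AP, which presents arachidonic acid for leukotriene synthesis, rose by 8.67 ± 0.85 (edgeR adjusted p = 0.005). The neutral amino acid transporter SLC6A17 (chromosome 1, 110150486 to 110202202) gained 8.08 ± 0.89, and the cytokine IL1B gained 8.07 ± 1.13. TNN, encoding the matrix protein tenascin-N, rose by 7.90 ± 0.77, and C6orf58 by 7.12 ± 0.95. HYAL4, a chondroitin hydrolase, had 3 counts over the CTRL-EC libraries, a ratio of 185 with a counting interval of 63.0 to 900.

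Genes that fell most in HUVEC R-VEC included the following. ITGB4 (chromosome 17, 75721328 to 75757818), a laminin receptor chain, fell by 6.80 ± 0.73 on the log2 scale (edgeR adjusted p = 0.00625), from 63.7 to 0.615 CPM. The tetraspanin TSPAN8 fell by 6.68 ± 0.84 and TRBC2, a T-cell receptor constant segment, fell by 6.34 ± 0.68. VCAN, the proteoglycan versican, fell by 6.27 ± 1.31 (edgeR adjusted p = 0.0499). EPHB6, an ephrin receptor without kinase activity, fell by 4.84 ± 0.58. SERPINB2, an inhibitor of plasminogen activators, fell by 3.88 ± 0.51, and the interleukin-33 receptor IL1RL1 fell by 3.81 ± 0.53. ITGA10 (chromosome 1, 145891208 to 145910189) fell by 3.53 ± 0.53 (edgeR adjusted p = 0.0195).

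Camera called 4 of the lists fixed beforehand in HUVEC R-VEC, none of them with an estimated correlation. Of 23 RAP1 signalling genes, 2 rose, none fell and 21 were not called, with 6 higher and 1 lower adjusted over the list alone. RASGRP2 and RASGRP3, activators of RAS and RAP1, rose by 4.74 and 2.69 in log2 fold change. The list median was 0.16 and its mean 0.69, so a few members carried much of the shift. Camera called the list higher (adjusted p = 0.00508, and adjusted p = 0.205 with an estimated correlation). Of 18 basement membrane genes, COL4A1 and COL4A2, the core collagen IV chains, rose by 3.16 and 2.76, while the laminin chain LAMA5 and TINAGL1 fell by 0.87 and 1.16. Adjusted over the list alone, 8 were higher and 2 lower (median 0.44; camera adjusted p = 0.000642, and adjusted p = 0.451 with an estimated correlation). Of 17 inflammatory activation genes, the neutrophil chemokines CXCL1 and CXCL3 rose by 5.02 and 3.65, and 9 were higher adjusted over the list alone. Their median log2 fold change was 2.16 (camera adjusted p = 1.14e-07, and adjusted p = 0.451 with an estimated correlation). No cell cycle gene of 25 was called, but the list median was -1.69 (camera adjusted p = 2.45e-08, and adjusted p = 0.754 with an estimated correlation). The other 14 lists had camera adjusted p from 0.0907 to 0.768. Among them, median, mean and test did not share a sign for the mural, venous, angiocrine, glycolysis and cholesterol lists.

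Within lists that camera did not call, HUVEC R-VEC still had changed members. SOX7, an endothelial SOX factor, rose by 1.10 and the blood-forming factor LYL1 fell by 1.39. KLF2 fell by 2.95, whereas SEMA3G, a semaphorin of arterial endothelium, rose by 3.20. EFNB2, the arterial ephrin ligand, rose by 1.08, and LTBP4, a carrier of TGF-beta, fell by 1.79. ANGPT2, which loosens vessels for sprouting, rose by 3.07, and SEMA3F fell by 1.86. POSTN, the matrix protein periostin, rose by 5.28, SNAI2, a mesenchymal regulator, rose by 2.04, and the scavenger receptor STAB1 rose by 0.92. The glycolytic enzyme HK2 fell by 1.04 and the early response gene IER2 fell by 0.67. No pan-endothelial gene of 26 was called, with 6 higher and 2 lower adjusted over the list alone (median 0.10).

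The replicate block changed calls for list members in HUVEC while the camera calls stayed the same. In pan-endothelial genes it called 7 higher and 5 lower, including PECAM1 (0.91), KDR (0.89), VWF (1.51), CDH5 (0.71) and the nitric oxide synthase NOS3 (-1.53) in log2 fold change. RAP1 signalling then had 8 higher and 2 lower, with the effector RASSF5 at 3.52. Basement membrane had 9 higher and 3 lower, including SMOC1 at -2.57. Inflammatory activation had 9 higher and 1 lower, with the adhesion molecules VCAM1 and SELE at 4.32 and 4.63 and SELP at -2.02. Among cell cycle genes, 13 of 25 were lower, and 25 adjusted over the list alone. Arterial genes had 5 higher and 3 lower, with the Notch ligand DLL4 at 1.73, the gap junction gene GJA5 at 2.53 and HEY2 at -2.83. Flow-responsive genes had 3 higher and 4 lower, with KLF2 at -3.02 and KLF4 at -1.68.

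The adult comparison asked whether ETV2 acts alike in mature endothelium of 5 tissues, with tissue as a block. The Wnt antagonist FRZB and the Hedgehog modulator SCUBE2 were among the transcripts that rose most, and ITGB4, ITGA10 and KRT19 were among those that fell most. edgeR called 167 of 16303 genes, 101 higher and 66 lower in R-VEC. Without both cardiac libraries 11 genes were called, without aortic 15, without lung 37, without dermal 77 and without adipose 104. Without the tissue term, 4 genes were called.

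Besides ETV2 (8.88 ± 0.34, edgeR adjusted p = 0.000199), adult R-VEC gained several secreted factors. FRZB, a soluble Wnt antagonist (chromosome 2, 182833275 to 182867162), rose by 6.20 ± 0.97 (log2 fold change ± SE; edgeR adjusted p = 0.0392). ECM1, an extracellular matrix glycoprotein, rose by 5.83 ± 0.45 (edgeR adjusted p = 0.00495), from 3.78 to 210 CPM. SCUBE2, which helps release Hedgehog ligands (chromosome 11, 9020391 to 9138114), rose by 5.18 ± 0.28 (edgeR adjusted p = 0.000761). SLC6A17 rose by 4.82 ± 0.62, the adenylate cyclase ADCY1 by 4.6 ± 0.36, and the capillary carbonic anhydrase CA4 by 4.49 ± 0.69. The transcribed pseudogene ANKRD26P1 rose by 4.16 ± 0.50, and it shares reads with near-identical copies.

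Among the genes that fell most in adult R-VEC, LYPD1, a membrane-anchored modulator of acetylcholine receptors, fell by 3.69 ± 0.54. ITGB4 fell by 3.60 ± 0.55 (edgeR adjusted p = 0.0392), from 46.3 to 6.75 CPM. GGT5, which converts leukotrienes, fell by 3.30 ± 0.55, and the epithelial keratin KRT19 fell by 3.20 ± 0.26. GPIHBP1, the capillary anchor of lipoprotein lipase, fell by 3.10 ± 0.39. ITGA10 fell by 2.75 ± 0.42, TRNP1, a nuclear regulator of proliferation, fell by 2.68 ± 0.34, and the collagen cross-linking enzyme LOX fell by 2.67 ± 0.16 (edgeR adjusted p = 0.00142). LOX in CTRL-EC had a library at 406 CPM, apart from the rest.

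List results in adult R-VEC covered signalling, stroma and interferon genes. Of 23 RAP1 signalling genes, RASGRP3 and RASSF5 rose by 1.96 and 2.15, and 5 were higher and 2 lower adjusted over the list alone. Camera called the list higher (median 0.15, mean 0.43; adjusted p = 0.0136, and adjusted p = 0.612 with an estimated correlation). Of 13 mural and fibroblast genes, the collagen I chain COL1A2 fell by 2.18 and 3 were lower adjusted over the list alone. COL1A1 stood at -3.46, and camera called the list lower (median -0.51; adjusted p = 0.0136, and adjusted p = 0.675 with an estimated correlation). Of 12 flow-responsive genes, KLF2 fell by 1.71, and the prostaglandin transporter SLCO2A1 passed adjusted over the list alone at -1.21. Camera called that list lower (median -0.43; adjusted p = 0.0136, and adjusted p = 0.56 with an estimated correlation). None of 25 cell cycle genes was called (median -0.89; camera adjusted p = 3.01e-07, and adjusted p = 0.712 with an estimated correlation). None of 18 interferon response genes was called, and OAS2, an antiviral RNA sensor, passed adjusted over the list alone at 0.97. Camera called that list higher (median 0.50; adjusted p = 0.000912, and adjusted p = 0.684 with an estimated correlation). Of 3 blood cell markers, the lysosomal gene LAPTM5 rose by 1.27 (camera adjusted p = 0.000912, and adjusted p = 0.56 with an estimated correlation).

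Other lists had adult members past the threshold although camera adjusted p ran from 0.154 to 0.971. LYL1 fell by 1.11, UNC5B, a netrin receptor, fell by 1.81, and SEMA3F fell by 1.61. The leukocyte adhesion gene SELP fell by 1.78. STAB2, a sinusoidal scavenger receptor, rose by 3.59, and TGFB2 rose by 1.10. No pan-endothelial gene of 26 was called, with 1 higher and 3 lower adjusted over the list alone. The inflammatory list had a median of 0.04 and a downward test.

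HUVEC and adult cells shared direction for many genes. Across 14879 genes tested in both, log2 fold changes had r = 0.673 and rho = 0.518, and genes are not independent replicates. Among called genes, 30 were higher in both, against 1.3 if the calls were independent, and 16 were lower in both, against 0.4. Fisher's exact test, two-sided across genes, gave p = 2.75e-33 and p = 3.77e-21. No gene was called in opposite directions, against 1.6 if independent. ETV2, SLC6A17, ITGB4 and ITGA10 were among the shared genes. The comparisons shared no library.

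**Figure D2:**
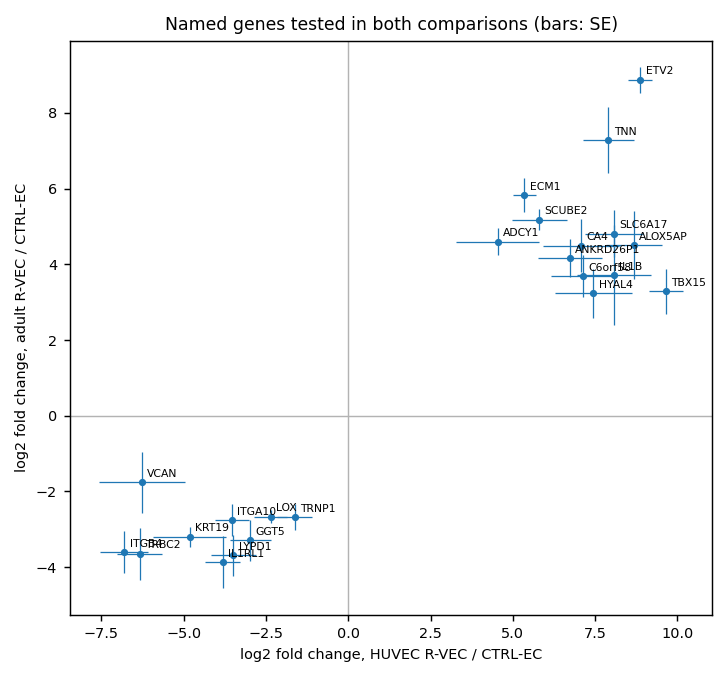
Log2 fold change (R-VEC against CTRL-EC) with SE bars in HUVEC and in adult cells for genes named in either comparison and tested in both, chosen as called in at least 1 of them. ITGB4 lies at -6.80 in HUVEC and -3.60 in adult cells.

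Whether the effect of ETV2 differed between HUVEC and adult cells was tested as an interaction. edgeR called 0 of 17651 genes, while 1134 had an unadjusted p under 0.05 and DESeq2 called 32. With the HUVEC replicate block, edgeR called 3 genes. These were the stress kinase MAP3K5, lower in HUVEC R-VEC by comparison (-1.74 ± 0.17, edgeR adjusted p = 0.0117), and POSTN and the adhesion receptor ADGRL3, higher (6.50 ± 0.77 and 3.15 ± 0.39, edgeR adjusted p = 0.0424 each). The inflammatory list differed by a median of 2.28 in log2 fold change (camera adjusted p = 1.29e-12, and adjusted p = 0.336 with an estimated correlation). CXCL1 and the NF-kappa-B inhibitor NFKBIA passed adjusted over the list alone, at 3.97 and 1.31. Basement membrane genes differed by 0.63 (camera adjusted p = 1.56e-07), with COL4A1 at 2.07, and mural and fibroblast markers by 0.53 (camera adjusted p = 0.0101). Both had adjusted p = 0.336 with an estimated correlation. Cell cycle genes differed by -0.69 (camera adjusted p = 0.00014, and adjusted p = 0.639 with an estimated correlation). Pan-endothelial genes differed by 0.23 (camera adjusted p = 0.035, and adjusted p = 0.468 with an estimated correlation), and this call ended with the block (adjusted p = 0.124). Tissue of origin and medium differed together between the HUVEC and adult libraries.

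The tube assay asked how R-VEC change as they assemble into tubes over 4 weeks. Without a block no single gene passed the test at any stage, and the replicate block called GPC1 and DIO2 between 4 weeks and 1 week. Camera called lists of inflammatory, glycolytic, interferon and cholesterol genes, none of which held with an estimated correlation (adjusted p from 0.208). At 1 week against flat, edgeR called 0 of 17533 genes, with 524 at an unadjusted p under 0.05, and DESeq2 called 35. Without R-VEC tubes 1 week 1, edgeR called 1 gene. At 4 weeks against flat, edgeR called 0, with 901 at an unadjusted p under 0.05, and DESeq2 called 89. Between 4 weeks and 1 week, edgeR called 0, with 877 at an unadjusted p under 0.05, and DESeq2 called 56. The replicate block called GPC1, a heparan sulfate proteoglycan (2.72 ± 0.17, edgeR adjusted p = 0.0166), and DIO2, which activates thyroid hormone (3.03 ± 0.24, edgeR adjusted p = 0.041), both higher at 4 weeks than at 1 week. Neither block call of this comparison was made without the libraries of any 1 replicate number.

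At 1 week, lists of stress, adhesion and metabolic genes stood higher than at the flat start. Of 18 inflammatory genes, 4 were higher adjusted over the list alone, including SELE (3.70) and CXCL3 (2.82) in log2 fold change (camera adjusted p = 9.36e-14, and adjusted p = 0.208 with an estimated correlation). Of 17 glycolysis and hypoxia genes, 6 were higher adjusted over the list alone, including lactate dehydrogenase LDHA (1.49), PFKFB4 (1.75) and the mitophagy gene BNIP3 (1.53), with camera adjusted p = 7.29e-19 and adjusted p = 0.208 with an estimated correlation. Of 16 immediate early and heat shock genes, 5 were higher adjusted over the list alone, including ATF3 (3.68), FOS (5.43) and FOSB (5.6), with camera adjusted p = 0.000131 and adjusted p = 0.437 with an estimated correlation. The median of that list was 0.12 and its mean 1.22. The apelin receptor APLNR (5.16) and the growth factor IGF2 (4.71) passed in their own lists. Interferon response (median 1.21; camera adjusted p = 2.22e-09), cell cycle (0.65; 0.000312), flow-responsive (0.00, mean 0.41; 0.0137) and RAP1 signalling (0.08; 0.0245) were called higher. Cholesterol synthesis was called lower (-0.46; camera adjusted p = 0.000378). Their adjusted p was 0.54 to 0.594 with an estimated correlation. The block ended the RAP1 call (adjusted p = 0.0598). It left 2 inflammatory, 5 glycolysis and 5 immediate early genes past adjusted over the list alone.

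At 4 weeks, interferon genes made up the largest list shift against the flat start. Of 18 interferon genes, 16 were higher adjusted over the list alone, among them IFI27 (2.04), IFI6 (3.41), IFI44L (4.51) and IFI44 (1.75), with camera adjusted p = 1.84e-21 and adjusted p = 0.229 with an estimated correlation. With the replicate block, 0 of the 18 passed adjusted over the list alone, while the median was 2.03 and camera still called the list (adjusted p = 7.39e-16). Inflammatory genes (median 1.19; camera adjusted p = 3.48e-10), tip cell genes (0.34; 0.00193), glycolysis (0.33; 0.00393), immediate early genes (0.29; 0.00427) and basement membrane (0.26; 0.01) were called higher. Arterial genes (-0.52; camera adjusted p = 5.72e-05), cholesterol synthesis (-0.71; 3.86e-07), cell cycle (-0.16; 0.00446) and hemato-vascular factors (-0.24; 0.0152) were called lower. Their adjusted p was 0.229 to 0.611 with an estimated correlation. Adjusted over its list alone, the vasodilator ADM stood at 1.09, the glucose transporter SLC2A1 at 1.84, KLF2 at 1.98, CYP1B1 at 3.08, the sialomucin CD34 at 2.33 and SEMA3G at -2.50. With the block, camera also called pan-endothelial genes higher (adjusted p = 0.0331, against 0.0527 without the block, where adjusted p = 0.413 with an estimated correlation).

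Between 4 weeks and 1 week, cell cycle (median -0.86; camera adjusted p = 2.05e-09), glycolysis (-0.59; 4.78e-06) and arterial genes (-0.40; 0.00612) were called lower. Interferon response (1.10; camera adjusted p = 6.18e-06) and EndMT factors, which drive endothelial to mesenchymal change (0.32; 0.0374), were called higher. All had adjusted p = 0.645 with an estimated correlation. APLNR (-6.11), the aldolase ALDOC (-2.24) and ADM (1.28) passed adjusted over their lists alone. The block added a cholesterol synthesis call (camera adjusted p = 0.0426, against 0.103 without the block, where adjusted p = 0.709 with an estimated correlation). In the tube assay, median, mean and test did not share a sign for the mural, angiocrine, venous, blood cell and flow-responsive lists in at least 1 comparison.

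Fresh against cultured HUVEC asked what culture itself does to endothelial transcripts. All 25 cell cycle genes and 13 of 15 cholesterol synthesis genes rose with culture, and 13 of 15 mural and fibroblast genes fell. edgeR called 9950 of 15332 genes, 5025 higher and 4925 lower in culture. Fresh cells were sorted for VE-cadherin and CD31, and no sort is given for cultured cells, so effects of sorting and of culture were not separated. Several transcripts typical of stroma and blood were among those higher in fresh cells.

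Among the genes that rose most with culture, MMP1, an interstitial collagenase (chromosome 11, 102789920 to 102798160), rose by 12.24 ± 1.40 (log2 fold change ± SE; edgeR adjusted p = 2.73e-05), from 3.66 to 17750 CPM. SERPINB2 rose by 11.80 ± 0.56 (edgeR adjusted p = 9.6e-08). The adhesion-linked receptor CDCP1 had 1 count over the fresh libraries, a ratio of 13800 (counting interval 2480 to 545000). KIF19, a kinesin, had 1 count (ratio 5200, 933 to 206000), and the TNF-family ligand TNFSF18 had 2 counts (ratio 3460, 957 to 28600). MYEOV, RNF182 and the nuclear receptor NR5A2 had 0 counts in all fresh libraries and were at least 820-fold, 587-fold and 386-fold higher, against 3 counts over the group. Without cultured 3 the value was 392 for MYEOV and 8320 for CDCP1, and without cultured 2 it was 192 for NR5A2.

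Among the genes that fell most in culture, ELN, the elastin gene (chromosome 7, 74027789 to 74069907), fell by 12.29 ± 1.54 (edgeR adjusted p = 5.08e-05), from 16420 to 3.32 CPM. OMD, a small leucine-rich proteoglycan, fell by 12.76 ± 0.79 (edgeR adjusted p = 4.08e-07). The Wnt antagonist SFRP5 and the venular chemokine receptor ACKR1 each had 1 count in culture, with ratios of 23900 (4290 to 945000) and 17300 (3110 to 684000). INMT, an indole methyltransferase, had 0 counts in culture and was at least 3520-fold lower. C3orf36, the matrix gene MXRA5 and the sulfotransferase SULT1C2 had 0 counts as well and were at least 1040-fold, 938-fold and 897-fold lower. MXRA5 had a fresh library at 50.2 CPM, apart from the rest. Without fresh 4 the value was 606 for MXRA5 and 8670 for ACKR1.

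All 25 cell cycle genes rose, with the mitotic kinase PLK1 at 5.25 and the nucleotide enzyme TYMS at 4.24 (median 4.24; camera adjusted p = 1.26e-28, and adjusted p = 0.023 with an estimated correlation). Of 15 cholesterol synthesis genes, 13 rose and none fell, with LSS at 4.07 (median 2.67; camera adjusted p = 1.66e-11, and adjusted p = 0.023 with an estimated correlation). Of 15 mural and fibroblast genes, 13 fell and 1 rose, with the proteoglycan DCN at -10.51 and COL1A1 at -8.79. Their median was -4.85, or -4.83 with the gene at 0 counts set to its bound (camera adjusted p = 3.14e-07, and adjusted p = 0.0214 with an estimated correlation). These were the only 3 of 66 list calls over the 8 comparisons that held with an estimated correlation, and none of the 5 interaction list calls did. Of 13 tip cell genes, 11 rose, including the peptide APLN (11.48) and the growth factor PGF (9.11), with camera adjusted p = 1.58e-06 and adjusted p = 0.0906 with an estimated correlation. Of 17 immediate early and heat shock genes, 14 fell, including FOSB (-7.56) and the RNA-binding ZFP36 (-6.71), with camera adjusted p = 1.83e-08 and adjusted p = 0.0906 with an estimated correlation.

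Further lists fell in culture. Of 18 interferon genes, 16 fell, including IFI44L at -7.10 (camera adjusted p = 2.08e-05, and adjusted p = 0.318 with an estimated correlation). Of 20 angiocrine genes, 13 fell and 3 rose, with the Wnt agonist RSPO3 at -8.27 and DKK1 at 8.83 (camera adjusted p = 0.00339, and adjusted p = 0.0906 with an estimated correlation). Of 15 flow-responsive genes, 11 fell and 4 rose, with KLF4 at -6.64, the arginine pathway enzyme ASS1 at -9.31 and HMOX1 at 6.48 (camera adjusted p = 0.0332, and adjusted p = 0.422 with an estimated correlation). Of 17 inflammatory genes, 10 fell and 2 rose, with IL6 at -2.66 and CXCL8 at 4.94 (camera adjusted p = 0.0194, and adjusted p = 0.422 with an estimated correlation). Of 7 blood cell markers, 4 fell, including CD14 at -5.66 (camera adjusted p = 0.0436, and adjusted p = 0.318 with an estimated correlation).

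Identity genes went both ways, and camera did not call their lists without a block (adjusted p from 0.0507 to 0.828). Of 26 pan-endothelial genes, 6 rose and 13 fell, with the VEGF receptor KDR at 7.99, the tight junction gene CLDN5 at 4.65, the fenestral gene PLVAP at -7.82 and RAMP2 at -6.35. Of 22 hemato-vascular factors, 6 rose and 12 fell, with SOX17 at 7.80 and LMO2 at -2.71. Arterial genes had 6 that rose, such as the chemokine receptor CXCR4 (8.0), and 9 that fell, such as the elastic fibre gene FBLN5 (-9.97). Venous and lymphatic genes had 3 that rose and 8 that fell, with APLNR at -10.74. With the replicate block, camera called that list lower (adjusted p = 0.0162, against 0.212 without the block, where adjusted p = 0.51 with an estimated correlation). Of 22 RAP1 genes, 7 rose and 7 fell, and of 18 basement membrane genes, 8 rose and 8 fell, with fibronectin FN1 at -5.73. Of 14 EndMT factors, 4 rose and 4 fell, with TGFB2 at -9.69. Of 17 glycolysis genes, 7 rose and 4 fell, with ENO1 at 2.59. Adjusted over the list alone, 11 inflammatory genes fell and 9 basement membrane genes rose, and the counts of the other lists in culture were the same. Median, mean and test did not share a sign for the hemato-vascular and basement membrane lists.

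**Figure D3:**
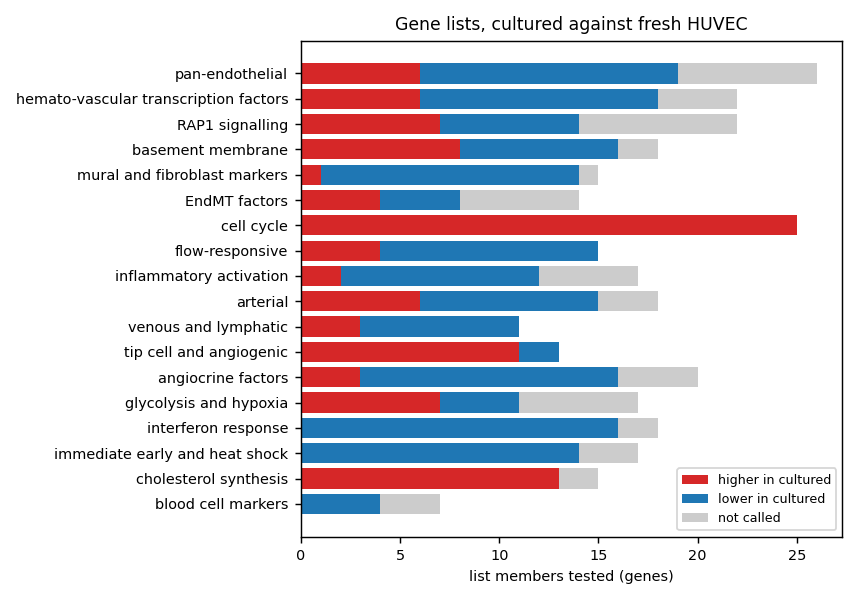
Number of tested members of each gene list (bars, genes) that edgeR called higher, called lower or did not call in cultured against fresh HUVEC. All 25 cell cycle genes were called higher, and 13 of 15 mural and fibroblast genes were called lower.

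R-VEC from plugs against R-VEC before injection asked what 1 month in a living host changes. Of the listed genes, 14 of 18 mural and fibroblast, 9 of 11 blood cell and 12 of 17 immediate early genes rose, and 12 of 25 cell cycle and 4 of 26 pan-endothelial genes fell. None of these list calls held with an estimated correlation (adjusted p from 0.0972 to 0.876). edgeR called 4048 of 16760 genes, 3186 higher and 862 lower in plugs. The count was 6100 and 1412 without plug 2 and plug 3, and 896 and 931 without pre-plug 1 and 2, and without plug 1 the lower genes numbered 1426. Of 1947 processed pseudogenes tested, 86.1% were called higher, against 9.7% of 13072 protein-coding genes. In cultured against fresh HUVEC these shares were 22.6% of 341 and 36.2% of 12912. Pseudogenes high only in plugs can pass the count filter through the plugs, so a high share there was partly fixed beforehand. The libraries also differed in depth and in mitochondrial share (1.28 to 13.28% in plugs, 3.04 and 4.04% before). Plug cells were sorted for GFP from the implants, and effects of this handling and of the host were not separated.

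Genes that rose most in plugs included stromal, macrophage and copy genes. COL6A3, a collagen VI chain (chromosome 2, 237324003 to 237414375), had 2 counts before injection, a ratio of 13400 (counting interval 3690 to 110000). With 0 counts before injection, F13A1, the coagulation factor XIII chain found in macrophages, was at least 9070-fold higher. The macrophage pore protein MPEG1 was at least 1030-fold higher, cardiac actin ACTC1 at least 1060-fold and the matrix gene ASPN at least 1600-fold. RPL10L, FTLP and POTEF are near-identical copies of RPL10, FTL and ACTB, but took few reads outside plugs. In the other 37 human libraries FTLP and POTEF amounted to at most 0.00139 and 0.00244% of FTL and ACTB. RPL10L and FTLP were at least 3860-fold and 2440-fold higher, and POTEF, with 1 count before injection, had a ratio of 9920 (1780 to 392000). Single libraries moved these values, which pool the counts of the 3 plugs. Without plug 1 they were 36700 for COL6A3, 21900 for F13A1, 3110 for MPEG1, 3150 for ACTC1, 8320 for RPL10L, 6270 for FTLP and 28600 for POTEF. Without plug 3 they were 5040 for F13A1, 687 for ACTC1 and 1290 for FTLP. RPL10L amounted to 17.3, 57.5 and 54% of RPL10 in the 3 plug libraries and to at most 0.00665% in the other 37 human libraries.

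Genes that fell to 0 counts in plugs were of lower abundance, so their bounds were smaller. SUSD5, a membrane protein, was at least 186-fold lower, the synaptic adhesion gene NLGN1 at least 113-fold, and PLPPR1 at least 45.5-fold. B4GALNT4, TMEM200A and the dioxin-induced CYP1A1 were at least 37.3-fold, 35.4-fold and 31.1-fold lower. TMEM59L and the forkhead factor FOXL1 were at least 30.2-fold and 29.9-fold lower. Without pre-plug 1 the bound was 58.7 for NLGN1, 24.6 for PLPPR1 and 24.1 for B4GALNT4.

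Lists in plugs described stroma, blood, stress and growth. Of 18 mural and fibroblast genes, 14 rose and 15 were higher adjusted over the list alone, with COL1A1 at 12.40, COL1A2 at 11.21 and the pericyte receptor PDGFRB at 11.91. Their median was 5.73 (camera adjusted p = 4.12e-09, and adjusted p = 0.832 with an estimated correlation). Of 11 blood cell markers, 9 rose and 10 were higher adjusted over the list alone, with the myeloid factor SPI1 at 12.42 and the leukocyte phosphatase PTPRC at 13.58. Their median was 9.49, or 8.41 with the gene at 0 counts set to its bound (camera adjusted p = 3.54e-07, and adjusted p = 0.0972 with an estimated correlation). Of 17 immediate early and heat shock genes, 12 rose, also adjusted over the list alone, with FOSB at 11.82, FOS at 10.53 and EGR2 at 10.02. Their median was 3.75 (camera adjusted p = 3.18e-08, and adjusted p = 0.0972 with an estimated correlation). Of 25 cell cycle genes, 12 fell and 14 were lower adjusted over the list alone, with TYMS at -3.17 and CCNB1 at -4.01 (median -2.10; camera adjusted p = 5.49e-06, and adjusted p = 0.87 with an estimated correlation).

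Of 26 pan-endothelial genes in plugs, 4 fell and 1 rose, with the clotting factor VWF at -3.82, ICAM2 at -3.32, EMCN at -2.83 and ENG at -2.90. Adjusted over the list alone, 5 were lower and 3 higher, and camera called the list lower (median -1.33; adjusted p = 0.00698, and adjusted p = 0.876 with an estimated correlation). CDH5 stood at 1350, 60.7 and 686 CPM in the 3 plugs against 2180 and 2250 CPM before injection. COL1A1 stood at 5420, 13900 and 3860 CPM against 1.28 and 1.48 CPM. Lists not called by camera (adjusted p from 0.114 to 0.771) also held changed members. The flow-induced KLF4 rose by 8.35, the arterial gap junction gene GJA4 by 5.34, RASGRP2 by 5.6, UNC5B by 7.12 and the chemokine CXCL12 by 9.33. TINAGL1 fell by 4.15, MMRN1 fell by 5.79, BMP6 fell by 6.89 and the Wnt antagonist DKK1 fell by 9.14. Median, mean and test did not share a sign for the basement membrane, inflammatory, tip cell, angiocrine and interferon lists.

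**Figure D4:**
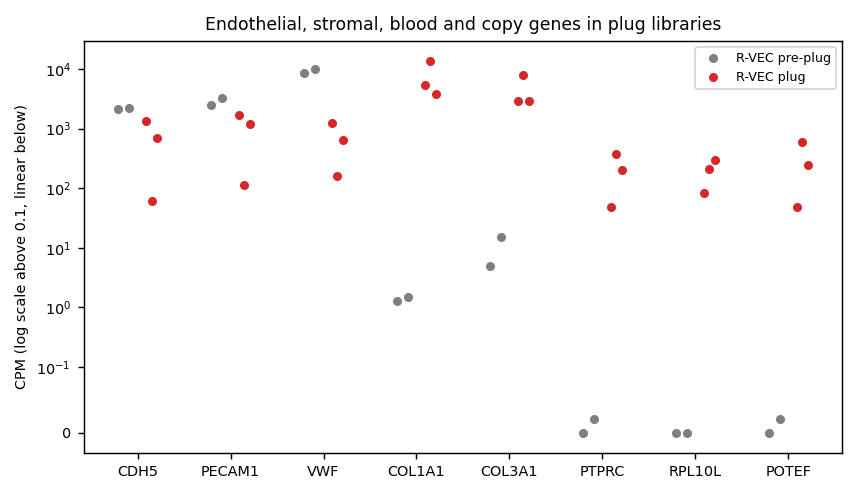
Level in CPM of endothelial, stromal, blood cell and copy genes in each plug and pre-plug library (points; axis logarithmic above 0.1 CPM and linear below). COL1A1 lies at 3860 CPM or more in the 3 plug libraries and at 1.48 CPM or less before injection.

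Genes that differ between fresh and cultured HUVEC were followed in R-VEC as sets of 200. In plugs, 65 of 96 tested genes highest in fresh HUVEC rose and 5 fell (median 6.28; camera adjusted p = 7.42e-15, and adjusted p = 0.198 with an estimated correlation). Of 166 genes highest in culture, 52 fell and 7 rose (median -1.70; camera adjusted p = 4.36e-10, and adjusted p = 0.189 with an estimated correlation). Adult R-VEC had the cultured set lower (median -0.23; camera adjusted p = 0.0026, and adjusted p = 0.57 with an estimated correlation). The fresh set stood lower there too (median -0.18; camera adjusted p = 0.0503). It was called lower with 100 genes (camera adjusted p = 0.0389, and adjusted p = 0.459 with an estimated correlation) but not with 500 (camera adjusted p = 0.104). Tubes at 4 weeks had the cultured set higher (median 0.34; camera adjusted p = 0.000238, and adjusted p = 0.442 with an estimated correlation), and the fresh set had a median of 0.59 there (camera adjusted p = 0.0503). HUVEC R-VEC showed neither set called (camera adjusted p = 0.71 and 0.0629), but the cultured set was called lower with 100 and with 500 genes (camera adjusted p = 0.00818 and 0.00499, and adjusted p = 0.459 and 0.717 with an estimated correlation). In tubes the cultured set was not called with 500 genes (camera adjusted p = 0.22), while the fresh set was called higher with 100 and with 500 (camera adjusted p = 0.0312 and 0.00194, and adjusted p = 0.126 and 0.0816 with an estimated correlation). The processed pseudogene share in plugs applies to these sets too.

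The mouse comparison asked what marks CD31+ cells that express Etv2 at E9.5. The vascular transcription factor genes Foxc2 and Lmo2 rose in Venus-positive cells. Pluripotency and germ cell genes and some blood progenitor and epithelial genes fell, that is, they were higher in Venus-negative cells. edgeR called 476 of 17825 genes, 115 higher and 361 lower in Venus-positive cells. With n = 2 per group, single libraries moved this count to 2335 and 4210 without Venus-negative 1 and 2, and to 2 and 125 without Venus-positive 1 and 2.

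In Venus-positive cells, Etv2 rose by 7.61 ± 0.63 (log2 fold change ± SE; edgeR adjusted p = 0.0261). C1ql2, a synaptic complement-like protein, rose by 8.66 ± 0.97 (edgeR adjusted p = 0.0316), and the gelatinase Mmp9 (GRCm38 chromosome 2, 164940780 to 164955850) rose by 8.06 ± 0.50, from 0.387 to 104 CPM. The cyclic nucleotide phosphodiesterase Pde2a rose by 5.64 ± 0.81, Lbx1, a homeobox gene of migrating muscle precursors, by 5.52 ± 0.53, and Scand1 by 5.10 ± 0.35. The lymphocyte adaptor Lax1 rose by 5.06 ± 0.73, and the synaptic protein Prr7 by 4.73 ± 0.46.

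All 8 genes that fell most were pluripotency or germ line genes. Pou5f1, the OCT4 gene (GRCm38 chromosome 17, 35506018 to 35510772), fell by 10.41 ± 0.87 (edgeR adjusted p = 0.0261), from 127 CPM in Venus-negative to 0.0865 CPM in Venus-positive cells. Nanog fell by 8.87 ± 0.84 and Prdm14, a repressor needed for germ cell fate, fell by 8.33 ± 0.97. The X-linked homeobox gene Rhox6 fell by 7.92 ± 0.87. Dppa3, Rhox9 and Dppa5a had 0 counts in Venus-positive cells and were at least 1470-fold, 955-fold and 708-fold lower. Utf1, a chromatin factor of pluripotent cells, had 1 count there, a ratio of 1720 (308 to 68000). Without Venus-negative 2 the value was 922 for Dppa3, 345 for Dppa5a and 1050 for Utf1.

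Mouse lists set vascular factors against blood and epithelium. Of 22 hemato-vascular factors, Foxc2 and Lmo2 rose by 4.03 and 1.63 and Runx1, the master of blood emergence, fell by 3.84, with 9 higher and 1 lower adjusted over the list alone (median 1.76; camera adjusted p = 2.73e-08). No pan-endothelial gene of 26 was called without a block (median 1.75; camera adjusted p = 3.18e-07). No arterial gene of 18 was called, and 5 were higher adjusted over the list alone, including Sox17 at 4.17 (median 1.19; camera adjusted p = 2.02e-05). EndMT factors (median 0.81; camera adjusted p = 0.000278) had Snai1 and Twist1 higher by 2.23 and 1.85. Endocardial genes, which line the heart, had a median of 1.23 (camera adjusted p = 7.82e-05). Each of these had adjusted p = 0.47 with an estimated correlation.

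Camera called blood, epithelium and mural lists lower in Venus-positive cells, each with adjusted p = 0.47 with an estimated correlation. Of 17 blood progenitor and myeloid genes, 6 fell in Venus-positive cells, and 14 adjusted over the list alone, including the platelet integrin Itga2b (-3.66) and Gfi1b (-6.28), with camera adjusted p = 9.34e-15. Of 13 erythroid genes, 3 fell, and 12 adjusted over the list alone, including Gata1 (-6.85) and the embryonic globin Hbb-y (-5.88), with camera adjusted p = 1.32e-11. Of 14 epithelium and endoderm genes, 5 fell, and adjusted over the list alone 11 fell and 1 rose. Cdh1, Epcam and Esrp1 stood at -4.53, -4.42 and -5.86 (camera adjusted p = 1.32e-11). Of 18 mural and fibroblast genes, Postn fell by 4.48, and 4 were higher and 9 lower adjusted over the list alone (median -1.65; camera adjusted p = 0.00842). Camera also called venous and lymphatic (adjusted p = 0.0158), cardiomyocyte (0.00842), mesenchyme and somite (0.036), tip cell (0.036), flow-responsive (0.0363), cholesterol synthesis (0.0363) and angiocrine genes (0.0492) higher, and neural (0.036) and interferon genes (0.027) lower. Their adjusted p was 0.47 to 0.558 with an estimated correlation. Among these, Nrp2 rose by 2.18, Myh7 by 2.96 and Igfbp4 by 2.43, while Pdpn fell by 3.07 and Sox2 fell by 4.33. Median, mean and test did not share a sign for the inflammatory and glycolysis lists.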

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

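The interaction with the HUVEC replicate block was chosen only after its result without the block was seen, and so were both cell cycle tests. Of 70 groups of 4 or 5 libraries tested for a library far from the others, 5 stood out, and chance alone gives about 1 in 20.

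In adult R-VEC, the adipose library detected 28195 genes against 26242 in the next, and in adult CTRL-EC the adipose library detected 28162 against 26227. These 2 libraries also had the highest mitochondrial shares of their groups (9.14 and 5.4%). Each adult group held 1 library per tissue, so a library standing out there cannot be told apart from its tissue. TRBC2 in HUVEC CTRL-EC had a library at 9.86 CPM, below the next at 44 CPM. LOX in adult CTRL-EC had a library at 406 CPM, above the next at 158 CPM. MXRA5 in fresh HUVEC had a library at 50.2 CPM, above the next at 17.6 CPM. No explanation was tested for these.

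For 5 lists camera called a difference of the R-VEC effect between HUVEC and adult cells, none with an estimated correlation (adjusted p from 0.336 to 0.639), and the pan-endothelial call ended with the HUVEC block (adjusted p = 0.124). Median differences in log2 fold change were 2.28 for inflammatory activation, 0.63 for basement membrane, 0.53 for mural and fibroblast markers, -0.69 for cell cycle and 0.23 for pan-endothelial genes. With the HUVEC block, 3 genes differed: MAP3K5 (-1.74), POSTN (6.50) and ADGRL3 (3.15). Their edgeR adjusted p was 0.0117, 0.0424 and 0.0424 with the block and 0.419, 0.138 and 0.765 without it. For POSTN, the edgeR adjusted p ran up to 1 without the tissue block, while DESeq2 called it. Other splits say nothing here, since the real count without the block was 0 and 100 of 100 splits are then as large (highest other 64). Tissue of origin and medium differed together between HUVEC and adult libraries, so no explanation was tested.

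The cell cycle list, chosen from the 18 after medians were seen, was shifted lower in R-VEC in both comparisons (adjusted p = 0.754 and 0.712 with an estimated correlation), and not by a few members, as 25 of 25 were negative in both. Chance differences in growth between cultures stay open: 7 of 9 pairs were lower, with a mean of -1.14 and a range from -3.09 to 0.28. The exact two-sided sign-flip p was 0.0156, where 9 pairs allow 0.00391 at the smallest, and 0.0703 adjusted over the 18 lists. A list standing alone at that smallest p would also reach only 0.0703, so this test does not decide. RAP1 signalling (9 of 9 pairs higher, mean 0.38), flow-responsive genes (8 of 9 lower, mean -0.41) and blood cell markers (8 of 9 higher, mean 0.71) had the same adjusted value. A slower division of ETV2-expressing cells may explain the shift and stays untested.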

How the results depend on the processing

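Chosen only after results were seen were the HUVEC block in the interaction and leaving out numbered pairs under the block. No named gene changed sign under an alternative run on it. With the block, camera directions of 3 HUVEC lists (mural, glycolysis and cholesterol) and of the immediate early list in the interaction turned, none of them called either way, and the balance of higher and lower counts moved in several comparisons. RLE size factors and the filter at 1 CPM kept all counts within 1.5 times, as did the fits with only the 6 libraries of the compared tube stages. The counts of cultured against fresh HUVEC stayed so in every alternative run, with 9318 to 10783 called (4703 to 5223 higher, 4615 to 5560 lower) when a library was left out.

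DESeq2 called 1502 genes in HUVEC (835 higher, 667 lower), 1295 in adult cells (696, 599), 35 (32, 3), 89 (74, 15) and 56 (35, 21) in the tube assay at 1 week, at 4 weeks and between them, 2728 in mouse (1127, 1601), 32 in the interaction (25, 7) and 1332 lower in plugs. It shared 333 of the 338 HUVEC calls, all 167 adult, 3998 of 4048 plug and all 476 mouse calls. The cause was not tested. Its false calls on simulated data were more frequent, but those data followed edgeR's spread without tissue or replicate differences. They cannot say whether the added calls here are false.

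Without the low-count filter, adult cells gave 1589 calls (806, 783), the tube assay 6 (6 higher), 12 (11, 1) and 7 (3, 4), mouse 3502 (1656, 1846) and plugs 582 (488, 94). The cause was not tested. Removing the tissue block left 4 adult calls (4 higher, 0 lower), by construction with tissue differences in the spread.

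With the replicate block, HUVEC gave 3340 calls (1652, 1688), tubes at 4 weeks against 1 week 2 (2 higher), mouse 1743 (672, 1071) and the interaction 3 (2, 1). Mouse libraries rested on 2 pairs at a correlation of 0.143. There the block called 16 pan-endothelial genes higher and 1 lower, 14 hemato-vascular and 7 arterial genes higher, and ended the cholesterol list call (camera adjusted p = 0.0594). In cultured against fresh HUVEC, same-number correlations were 0.034 to 0.233 and others -0.171 to 0.092, below the limit in at least 1 pair, so the block was only an alternative. It gave 9949 calls, 9653 of them shared. Of the 4 fresh libraries, 3 correlated best with the cultured library of their own number, which hints at pairs. The block changed no other call of a count. No paired analysis was possible for plugs because the groups share only 1 replicate number in the labels.

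Leaving out a library or tissue gave these ranges: HUVEC 75 to 837 (50 to 511 higher, 17 to 326 lower), and with the block 1780 (878, 902) and 1024 (522, 502) without numbers 1 and 3, in a range of 609 to 2609 (320 to 1367, 289 to 1242). Adult cells gave 11 to 104 (10 to 63, 1 to 41), plugs 896 to 6100 (737 to 3946, 104 to 2154) and mouse 2 to 4210 (1 to 2235, 1 to 1975). The tube assay gave 0 to 1 at 1 week (0 to 1 higher, 0 lower), 0 to 0 in the other stages, and 0 to 1 between 4 weeks and 1 week with the block (0 higher, 0 to 1 lower). Where 1 library was left in a group, it was assumed to vary like the other group.

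With an estimated correlation, 3 of the 66 list calls of the 8 comparisons and 0 of the 4 culture set calls remained. Sets of 100 genes gave 7 culture set calls and sets of 500 gave 5, not all of them the same sets. Of the named genes and list members, DESeq2 made 97 stronger and 1 weaker, no filter 61 and 41, and leaving out a library 64 and 331, with 1973 the same. The block made 42 of these genes stronger and, of whole lists, ended RAP1 signalling at 1 week of tubes (camera adjusted p = 0.0598) and mouse cholesterol synthesis, no tissue block 25 weaker, the 1 CPM filter 4 weaker and RLE 2 stronger and 1 weaker. In plugs, 2-fold and 4-fold changes were recovered in 0% of simulated genes, and depth, spread and sample number were not separated as causes. The median of all genes moved to -0.246 in culture without the filter, in plugs to 0.184 without the filter and -0.182 at 1 CPM, and to -0.426 and -0.236 without plug 1 and plug 3.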

Other observations

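The tests of host reads in plugs and of 1 mouse library alone were chosen only after the results were seen.

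Plug and culture changes ran opposite to each other. Across 13810 genes, log2 fold changes of plugs against pre-plug and of cultured against fresh HUVEC had r = -0.376 and rho = -0.343, with genes not independent. Among genes called in both, 987 went in opposite directions, against 555.9 if the calls were independent. The loss of cell cycle transcripts such as TYMS and CCNB1 in plugs and their gain in culture is part of this. So are mural and fibroblast genes, of which 14 of 18 rose in plugs, while 13 of 15 fell and 1 rose in culture. Of blood cell markers, 9 of 11 rose in plugs and 4 of 7 fell in culture. The processed pseudogene share in plugs applies here too. Whether reads of other cells in the plug and fresh libraries account for the opposition was not tested. Both plug and fresh cells were sorted, and whether that handling plays a part was not tested either. HUVEC R-VEC ran weakly opposite to culture, at r = -0.21 across 14235 genes. Adult R-VEC did not by this correlation, at r = -0.036 across 14486 genes. Calls in opposite directions to culture numbered 130 in HUVEC R-VEC, against 92.1 if independent. In adult R-VEC they numbered 62, against 45.2.

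In mouse, 12 germ cell markers beyond the genes named above had negative fold changes in Venus-positive cells, and edgeR called 3 of them. Nanos3, an RNA-binding protein of germ cells, fell by 5.24, Dnd1, which guards germ line RNAs, fell by 3.72, and the nuclear receptor gene Esrrb fell by 4.78. The enzyme gene Alpl was not called, at 76.4 ± 25 CPM in Venus-negative and 13 ± 5.76 CPM in Venus-positive cells (SD, n = 2 each). Nor were Tfap2c, at 60.7 and 6.8 CPM, and Kit, at 145 and 107 CPM.

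Stromal and blood markers were higher in plugs than before injection. With the pre-plug libraries thinned to the depth of plug 3, the mural and fibroblast median was 6.41, above the 5.73 at full depth. Of the list, 13 members were called higher, so these calls did not need the full pre-plug depth. Over all genes the calls fell to 2202 (1883 higher, 319 lower). Thinning does not change the expected ratio of counts, so the median could not decide on library depth. Reads of mouse host cells counted on human genes remain a candidate source. Processed pseudogenes, on which reads of another species can land, were called higher 8.88 times as often as protein-coding genes, against 22.6% and 36.2% in the culture comparison. The count filter limits this ratio, as 1947 processed pseudogenes passed it in the plug comparison and 341 in the culture comparison. Many may have passed only by being high in plugs, so a high share was partly fixed beforehand. Ratios of a copy to its parent gene within a library do not depend on that filter. RPL10L amounted to 17.3, 57.5 and 54% of RPL10 in the 3 plugs, against at most 0.00665% in the other 37 human libraries. For FTLP and FTL these values were 3.08, 3.6 and 7.78%, against at most 0.00139%. These copies were named for being high in plugs, so they are not a random choice. The plug libraries were sorted for GFP, which would remove host cells but not RNA carried over from them, and COL1A1, COL3A1 and PTPRC reached 13900, 8010 and 371 CPM in plug 2. A change of the R-VEC themselves stays open, since no count here separates the species.

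Pluripotency and germ cell genes were higher in Venus-negative than in Venus-positive cells. Whether 1 library alone made this is not decided by the 8 named genes, 0 of which had a lowest Venus-negative library under 2 times the highest Venus-positive library, since they were chosen for groups that did not overlap. Primordial germ cells in the Venus-negative fraction are a candidate source, as a hypothesis with n = 2 per group, and Pou5f1 and Dppa3 averaged 127 and 55.2 CPM there. The 12 further markers had a median of -3.44, all 12 were negative, 3 were called lower and 10 passed adjusted over the list alone. The CD31 sort would keep such cells, which carry CD31, and a sort on a germ cell surface marker would remove them.

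Other splits of the same libraries gave a measure of chance. In cultured against fresh HUVEC, 1 of 35 splits, the real one, gave 9950 genes and the highest other gave 0. These splits ignore a pairing by number. The labels call the cultured cells matched, so if the numbers are pairs, chance cannot be excluded by this count. In adult cells, 1 of 100 splits gave as many as the real 167, and the highest other gave 61. Splits that put both libraries of a tissue on 1 side ignore the pairing by tissue, so they cannot exclude chance. Only 12 of the 100 part every tissue. The others of these 12 gave 0, and 12 are too few for a share under 0.05. In HUVEC R-VEC, 2 of 35 splits gave at least the real 338. The other, with 813 genes, exchanged R-VEC 3 and CTRL-EC 4, which points to a structure of the samples. Chance cannot be excluded by this count. Among the 8 splits that part every numbered pair, the others gave 0. With the block, 1 of 8 splits gave 3340 and the highest other 0, and 8 splits are too few for a share under 0.05. The 3 tube comparisons had 10 splits each, too few as well, with a real count of 0 (10 of 10 as large) and highest others of 30, 0 and 5.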
